A study of Arabidopsis thaliana with 12 samples.

How the data were processed

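RNA was sequenced from 4-d-old Arabidopsis seedlings of 4 genotypes, with 3 libraries each. Per the labels, seeds of Col-0 and the mutants lay on diluted Murashige and Skoog medium with 1% sucrose, for 2 d in the dark at 4 °C. Seedlings then grew at 22 °C with 16 h of light (100 µmol m-2 s-1) and 8 h of dark. Libraries were made from total RNA with an Illumina TruSeq kit. The deposited values are raw counts of reads per gene, 1 table per library. Per the labels, the authors trimmed reads with Trimmomatic, checked them with FastQC, aligned them to TAIR10 with TopHat2 2.1.1 and counted them with featureCounts. The annotation version, the strandedness, and the handling of reads that match several genes or overlapping genes are not stated. Each table was checked to hold whole numbers for the same 36917 gene IDs, unnormalised and with no summary lines.

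Groups were taken from the genotype labels and replicate numbers from the sample titles. For gun1 fug1, the number in the name of each count table is 1 above that in the title, and the titles are used here. Gene symbols, products and positions came from a TAIR10.1 annotation, which holds 36632 of the IDs. The other 133 plastid-encoded and 152 mitochondrion-encoded IDs were not in it, and plastid genes carry the names fixed in the gene lists. Of 6108 overlapping pairs of loci, 155 had over 1000 counts in each gene, and in 23 of these the pair lay within 0.2 log2 in every library, so that their reads cannot be told apart.

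Counts were analysed with edgeR 4.0.16 in R 4.3.3. Genes with low counts were removed by filterByExpr with the genotype as group, and libraries were scaled by TMM. A quasi-likelihood model with robust dispersion was fitted to all 12 libraries, with genotype as the only factor. The quasi-likelihood F test gave 6 comparisons: each mutant against wild type, gun1 fug1 against each single mutant, and the interaction, the gun1 fug1 minus fug1 difference less the gun1 minus wild type difference. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 over the 15371 genes tested. Levels are counts scaled to a common library size (CPM), and log2 levels use a prior count of 2. Shares of counts in organelle genes were compared by two-sided exact permutation tests.

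Before the data were examined, 25 gene lists, the tests, the rule for naming genes and most alternatives were fixed. The lists cover light harvesting, photosystems, carbon fixation, tetrapyrroles, retrograde regulators, and nuclear genes for plastid ribosomes, translation, transcription, proteases, chaperones and import. Others hold 4 groups of plastid-encoded genes, heat shock, cold, flavonoids, oxidative stress, glucosinolates, salicylate, the clock, root, seed storage and dividing cells. Of 416 list genes, 283 matched the annotation by symbol or synonym and 57 by product or alias, and 76 plastid genes could not be compared with it. The salicylate list had 1 tested member and was not tested. The other 24 were tested with limma 3.58.1 camera at a preset correlation of 0.01, adjusted over 144 tests, and beside it with an estimated correlation and with fry. Camera compares a list with all other genes. Counts of called members are given over all genes and adjusted over the list alone.

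For each comparison with wild type, the genes named are GUN1, FUG1, and the 6 largest rises and 6 largest falls among called genes that have a symbol, a mean of at least 50 counts in the higher group, and no overlap in CPM between the groups. From each list that camera called, or with at least 3 called members, the 2 members with the smallest p are named, and 1 more where the list did not move as one. For the other comparisons 3 rises, 3 falls and 1 or 2 members are named. Genes named outside this rule are said to be chosen after their values were seen.

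Alternatives were a replicate block, RLE and upper-quartile factors, organelle genes left out, DESeq2 1.42.0, limma-voom, no filter or a stricter filter (1 CPM in 3 libraries and a mean of 50 counts), stricter thresholds, fits of the compared groups alone, and leaving out each library. Those chosen after seeing the data stand with their results, among them library totals as scaling and the root list's mean (root score) as covariate. Correlations between fold changes were set beside 40 simulations with no effect, since the comparisons share the wild-type libraries.

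The procedure was tested on data simulated gene by gene from the fitted levels and spread, with 200 changed genes per comparison. In the 5 comparisons of groups, it recovered 68.3% to 85.5% of 4-fold changes, 17.2% to 29.2% of 2-fold and at most 3% of 1.5-fold. For the interaction these were 36.1%, 1.5% and 0%. Between 4 and 8 unchanged genes were called, and no sign was wrong. Camera found a list of 30 genes shifted by 0.5 log2 and called 1 of 20 unshifted lists at an unadjusted 0.05. It was not tested on correlated genes. Figures and tables used Python 3.11.15, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9. No library was left out of the reported values, and reads were not used here.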

Results

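RNA was sequenced from 4-d-old Arabidopsis seedlings of 4 genotypes: wild type (Col-0), the mutants gun1 and fug1, and the double mutant gun1 fug1. Each genotype had 3 libraries, named here by genotype and replicate (gun1 3). GUN1 encodes a pentatricopeptide repeat protein of the plastid that takes part in signalling from plastid to nucleus, and FUG1 encodes a plastid translation initiation factor. Total counts per library ranged from 8519197 to 12360838. Nothing in the labels says that the replicates are separate cultures, so p-values here measure the spread between these samples. Log2 fold changes are given with their standard error (SE) and normalised levels in CPM with their standard deviation (SD, n = 3).

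Plastid-encoded genes took most counts of every library. Their share was 70.7% ± 2.295 (SD, n = 3) in wild type, 75.6% ± 0.904 in gun1, 82.7% ± 1.49 in fug1 and 65.1% ± 10.05 in gun1 fug1. Against wild type, two-sided exact permutation p-values were 0.1, 0.1 and 0.7, where 0.1 is the smallest that 3 against 3 libraries can give. The gun1 fug1 mean minus wild type was -5.68 points, and -8.59, -8.57 and 0.12 without gun1 fug1 1, 2 or 3, so that its sign rests on gun1 fug1 3. With psbA, the most abundant gene, left out of all counts, the mean shares were 55.5%, 57.0%, 65.0% and 36.1%, and with psbA taken from plastid counts alone 36.4%, 32.6%, 32.2% and 19.2%. Mitochondrion-encoded genes took 0.413% ± 0.032 in wild type, 0.561% ± 0.059 in gun1, 0.473% ± 0.023 in fug1 and 0.631% ± 0.533 in gun1 fug1 (two-sided exact permutation p = 0.1, 0.1 and 0.5 against wild type). The last minus wild type was 0.218 points, and 0.126, 0.00978 and 0.519 without gun1 fug1 1, 2 or 3. The library gun1 fug1 3 stood apart from the other 11. In it 23881 genes had no count, against 13359 to 16417 in the others, and RR3 (AT2G41310) with the overlapping AT2G09250 took 31.0% of its counts. Its correlation with the other gun1 fug1 libraries was 0.72 and 0.73, where other pairs of replicates gave 0.92 to 0.97, across genes, which are not independent replicates. Its scaling factor was 0.0723, against 0.80 to 2.05 in the others, and many results are also given without it.

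**Figure D1:**
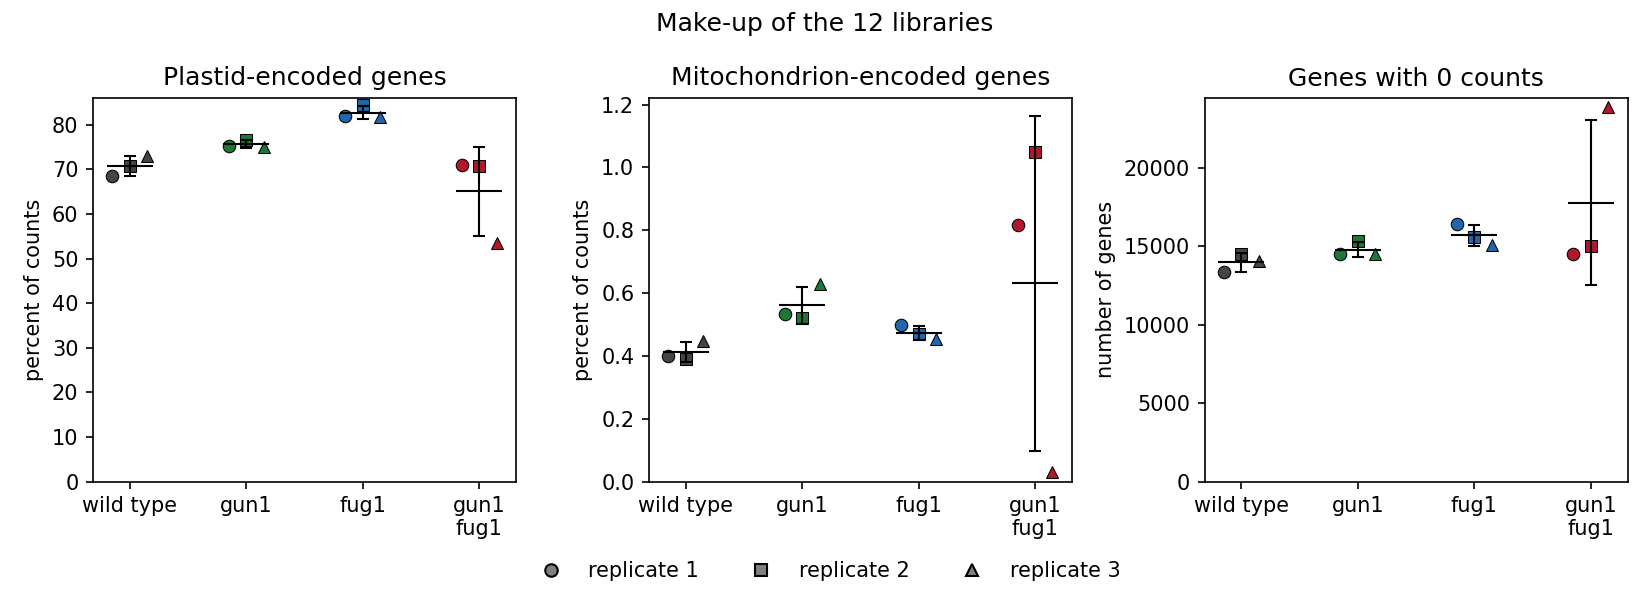
Plastid and mitochondrial shares of all counts (%) and the number of genes with 0 counts, by genotype; points are libraries (circle, square, triangle: replicates 1, 2, 3), bars means and error bars SD. The plastid share is 53.4% in gun1 fug1 3 and 68.5% to 84.4% in the others.

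Markers of another organ and of age were measured in the same libraries. The mean log2 level of 8 root and root hair genes, relative to wild type (0 ± 0.63, SD, n = 3), was 1.73 ± 1.14 in gun1, 2.28 ± 0.18 in fug1 and 2.39 ± 1.07 in gun1 fug1. For 6 seed storage and embryo genes it was 2.32 ± 0.50, 1.99 ± 0.38 and 1.84 ± 0.79 (wild type 0 ± 0.57). Within genotypes the root level varied from 0.51 to 2.77 in gun1 and 1.16 to 3.18 in gun1 fug1.

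The mutated genes come first. GUN1 (AT2G31400) lies on chromosome 2 from 13386954 to 13390854, minus strand, with 4 exons in its first model (TAIR10.1 annotation). Its level was 34.9 ± 4.73 CPM in wild type, 8.53 ± 1.18 in gun1, 28.3 ± 3.60 in fug1 and 8.99 ± 1.49 in gun1 fug1. It was lower than in wild type in gun1 (-2.03 ± 0.21, adjusted p = 4.45e-06) and in gun1 fug1 (-1.93 ± 0.22, adjusted p = 4.12e-06), and lower in gun1 fug1 than in fug1 (-1.63 ± 0.22, adjusted p = 0.000762), with no overlap between libraries. FUG1 (AT1G17220) lies on chromosome 1 from 5885007 to 5890500, plus strand, with 12 exons. Its level was 35.5 ± 9.07 CPM in wild type, 21.8 ± 10.6 in gun1, 8.73 ± 2.79 in fug1 and 11.3 ± 3.77 in gun1 fug1. It was lower than in wild type in fug1 (-2.02 ± 0.33, adjusted p = 0.00104) and in gun1 fug1 (-1.82 ± 0.35, adjusted p = 0.0018). GUN1 had -0.30 ± 0.20, adjusted p = 0.29 in fug1 against wild type, 0.10 ± 0.22, adjusted p = 0.849 in gun1 fug1 against gun1 and 0.41 ± 0.30, adjusted p = 0.475 in the interaction. Its value against gun1 changed sign without gun1 3 (-0.03), without gun1 fug1 2 (-0.10) and by library totals (-0.45). FUG1 had -0.70 ± 0.31, adjusted p = 0.188 in gun1 against wild type, -1.12 ± 0.35, adjusted p = 0.0876 in gun1 fug1 against gun1, 0.20 ± 0.36, adjusted p = 0.883 against fug1 (-0.02 without fug1 1) and 0.90 ± 0.47, adjusted p = 0.317 in the interaction. FUG1 passed in gun1 without gun1 1 (-1.19, adjusted p = 0.00576; 0.00576 to 0.965 over the alternatives), and against gun1 without gun1 3 (-1.39, adjusted p = 0.0153; 0.00127 to 0.941). In the interaction it passed without gun1 1 (1.36, adjusted p = 0.0418; 0.0418 to 0.9998). Scaled by library totals alone, the 5 calls ended, with log2 fold changes of -1.58 to -3.19 and adjusted p of 0.0717 to 0.99998. The FUG1 calls in fug1 and gun1 fug1 also ended with the root score as a covariate, with and without gun1 fug1 3, at log2 fold changes of up to -0.67 and -0.19 and adjusted p of up to 0.457 and 0.879.

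**Figure D2:**
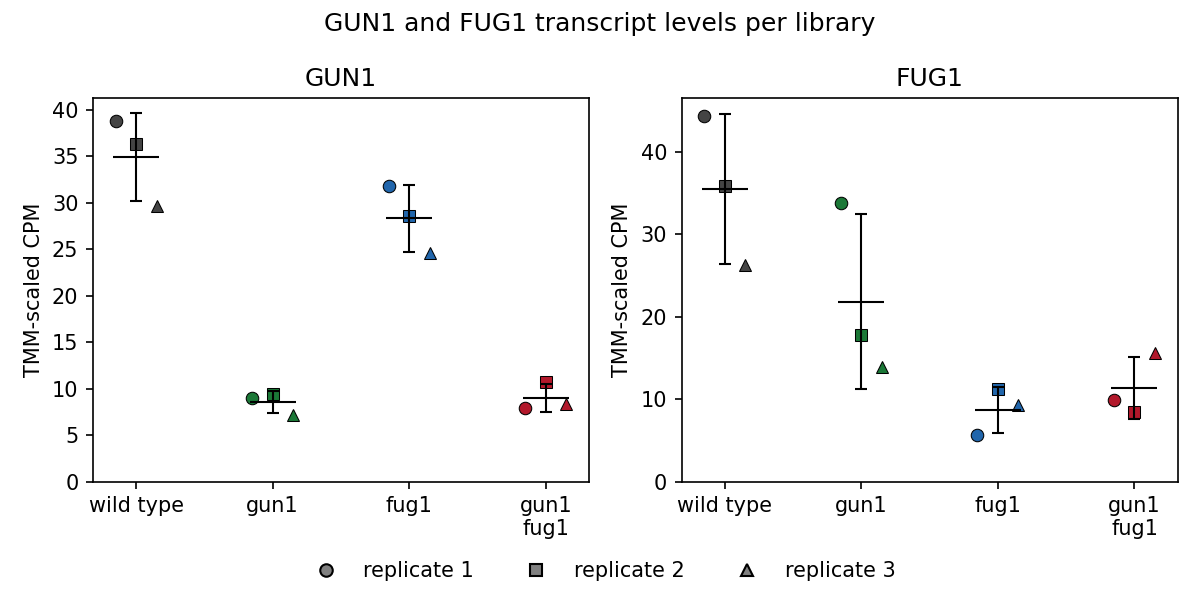
Levels of GUN1 and FUG1 (normalised CPM) by genotype; points are libraries, bars means and error bars SD. GUN1 averages 34.9 CPM in wild type and 8.53 in gun1, and FUG1 35.5 CPM in wild type and 8.73 in fug1.

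The comparison of gun1 with wild type asks what the gun1 mutation changes in seedlings grown without a plastid inhibitor. Against other genes, root genes (1 of 8 called) and seed storage genes (5 of 6) were higher as sets in gun1, and nuclear genes for plastid ribosomes (8 of 39), photosystems (5 of 32) and tetrapyrrole synthesis (3 of 28) lower. None of these set calls held with an estimated correlation (adjusted p = 0.294 to 0.62; given for lists as estimated-correlation p). SHV2 (AT5G49270, COBL9), needed for root hair growth, rose by 3.79 ± 0.61, adjusted p = 0.00131. The cruciferin gene CRA1 (AT5G44120), a seed storage protein, rose by 2.82 ± 0.29, adjusted p = 1.73e-05. The plastid ribosomal protein genes emb2184 (AT1G75350, RPL31) and RPL24 (AT5G54600) had -1.18 ± 0.22, adjusted p = 0.00312, and -1.37 ± 0.26, adjusted p = 0.00393. Of 15371 genes tested, 541 were higher and 372 lower, by library totals 0 and 1 (570 at an unadjusted p under 0.05 in edgeR, the only tool run so) and with the root score as a covariate 11 and 8. No run by library totals left out gun1 fug1 3, so its part in that loss of calls was not tested.

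Largest, in every comparison, means among the genes that the rule for naming admits. The largest rises were those of IRT2 (AT4G19680), a root iron transporter (3.86 ± 0.80), SQP2 (AT5G24140), similar to squalene monooxygenases (3.60 ± 0.51), and the cell wall genes XTH14 (AT4G25820; 3.37 ± 0.72) and AGP3 (AT4G40090; 3.32 ± 0.68). MRN1 (AT5G42600), marneral synthase of triterpene metabolism, and MOP10 (AT5G05500) followed (3.19 ± 0.43 and 3.17 ± 0.51). The largest fall was in SKIP5 (AT3G54480), an F-box gene (-5.20 ± 0.47, adjusted p = 9.99e-07). It had 1 or 2 counts per gun1 library, 69 to 112 in wild type and 34, 14 and 2 in gun1 fug1. ndhK (ATCG00430) and NdhM (AT4G37925), subunits of the plastid NDH complex, fell, at -2.33 ± 0.57 and -2.09 ± 0.47, and the peptide hormone gene RGF9 (AT5G64770) at -2.28 ± 0.49. CYSA (AT2G40880), a cystatin whose locus overlaps CYP98A3, fell, at -2.01 ± 0.34, adjusted p = 0.00122.

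Of 39 nuclear genes for plastid ribosomal proteins, 8 fell and 0 rose (14 adjusted over the list alone). Their median was -0.47 (camera adjusted p = 3.81e-09, estimated-correlation p = 0.537), and -0.29 without gun1 3. Of 32 photosystem and electron transport genes, 5 fell (6 alone), among them PSAN (AT5G64040) of photosystem I (-1.10 ± 0.27) and FNR2 (AT1G20020), a ferredoxin-NADP reductase (-1.09 ± 0.26). Their median was -0.24 (camera adjusted p = 2.30e-05, estimated-correlation p = 0.62), and -0.10 without gun1 3. Of 28 genes of tetrapyrrole synthesis, 3 fell (7 alone), including CHLI2 (AT5G45930) of magnesium chelatase (-1.28 ± 0.29; -1.93 without gun1 1) and the haem oxygenase gene TED4 (AT2G26670, HY1; -0.76 ± 0.19). Their median was -0.33 (camera adjusted p = 2.86e-05, estimated-correlation p = 0.526), and -0.55 without gun1 1 and -0.21 without gun1 3. Of 7 translation factors other than FUG1, 3 fell (6 alone), among them the release factor HCF109 (AT5G36170; -0.96 ± 0.27) and the elongation factor SCO1 (AT1G62750; -0.86 ± 0.26). Their median was -0.82 (camera adjusted p = 0.000319, estimated-correlation p = 0.304). Of 26 plastid proteases, 3 fell (4 alone), such as CLP2 (AT1G12410; CLPR2; -0.73 ± 0.21) and DEG5 (AT4G18370; -1.08 ± 0.32; -1.69 without gun1 1). Their median was -0.36 (camera adjusted p = 2.42e-05, estimated-correlation p = 0.44).

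The plastid transcription machinery had 1 lower gene of 20 (5 adjusted over the list alone), the sigma factor SIGA (AT1G64860; SIG1; -1.24 ± 0.34), beside SIGE (AT5G24120; SIG5) at -1.36 ± 0.42, adjusted p = 0.067. Its median was -0.53 (camera adjusted p = 0.0022, estimated-correlation p = 0.294). Of 11 plastid chaperones, the HSP90 gene CR88 (AT2G04030) fell (-1.04 ± 0.24; 3 alone), and CLPB3 (AT5G15450), whose locus overlaps EDL1, had -1.14 ± 0.33, adjusted p = 0.0538. Their median was -0.32 (camera adjusted p = 0.00417, estimated-correlation p = 0.481), and -0.48 without gun1 1. Leaving out wild type 1, gun1 2 or gun1 3 ended the call (adjusted p = 0.0511, 0.0584 and 0.109). Of 10 import genes, TIC56 (AT5G01590) fell (-0.68 ± 0.20; 1 alone), and emb1211 (AT5G22640; TIC100) had -0.59 ± 0.21, adjusted p = 0.0984. Their median was -0.35 (camera adjusted p = 0.0148, estimated-correlation p = 0.34). Of 10 plastid-encoded NDH genes, ndhK fell (2 alone), and ndhJ (ATCG00420) had -1.56 ± 0.47, adjusted p = 0.0794. Their median was -1.47 (camera adjusted p = 2.42e-05, estimated-correlation p = 0.521). By edgeR none of 17 plastid-encoded ribosomal protein genes passed, also over the list alone, with rpl32 (ATCG01020) at -3.93 ± 1.25 and rps2 (ATCG00160) at -1.81 ± 0.59. Their median was -1.02 (camera adjusted p = 0.000221, estimated-correlation p = 0.673). It turned to 0.76 with the root score as a covariate (camera adjusted p = 5.84e-05). None of 6 plastid genes read by the nuclear-encoded polymerase passed either, also over the list alone, with accD (ATCG00500) at -2.08 ± 0.90 and rpoC1 (ATCG00180) at -1.53 ± 0.94. Their median was -0.85 (camera adjusted p = 0.0449, estimated-correlation p = 0.728). Leaving out wild type 1, wild type 2, gun1 2, gun1 3, fug1 1 or fug1 3 ended the call (adjusted p = 0.0827, 0.055, 0.0524, 0.157, 0.0544 and 0.0504). It turned to 1.07 with the root score as a covariate (camera adjusted p = 0.00654).

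Of 6 seed storage genes, 5 rose (6 adjusted over the list alone), the oleosin gene OLEO1 (AT4G25140) by 2.45 ± 0.34, adjusted p = 0.000167. Their median was 2.58 (camera adjusted p = 2.42e-08, estimated-correlation p = 0.294). Of 8 root genes SHV2 rose (6 alone), and the root hair expansin EXPA18 (AT1G62980) had 4.03 ± 1.15, adjusted p = 0.0835. Their median was 2.64 (camera adjusted p = 8.45e-05, estimated-correlation p = 0.323), and 1.75 without gun1 3. The 11 other lists had camera adjusted p of 0.0592 to 0.911. Median, mean and test differed in sign for light-harvesting proteins (0.01, -0.03, downward), plastid-encoded photosynthesis genes (0.13, -0.17, downward), cold response (0.03, -0.01, downward), flavonoids (-0.15, 0.09, upward) and the clock (0.07, -0.25, downward).

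Numbers of higher and lower genes in gun1 moved by over 1.5 times when 1 library was left out: 129 and 93 (wild type 1), 101 and 53 (wild type 2), 694 and 647 (wild type 3), 939 and 814 (gun1 1), 248 and 83 (gun1 2), 118 and 65 (gun1 3) and 925 and 664 (gun1 fug1 3). Of 27 named genes called, 10 stayed called whichever 1 library was left out: SQP2, MRN1, MOP10, SKIP5, CYSA, emb2184, RPL24, SHV2, CRA1 and OLEO1. The other 17 lost the call, with adjusted p of up to 0.229 (wild type 1), 0.238 (wild type 2), 0.22 (gun1 2), 0.267 (gun1 3), 0.0683 (fug1 1), 0.0728 (fug1 2), 0.0717 (fug1 3), 0.0672 (gun1 fug1 1) and 0.0618 (gun1 fug1 2). Without gun1 fug1 3, camera also called carbon fixation (median -0.18, adjusted p = 0.049), at estimated-correlation p = 0.817.

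The comparison of fug1 with wild type asks what the fug1 mutation changes. As sets against other genes, nuclear genes for plastid ribosomes (15 of 39 called), translation factors (4 of 7), proteases (6 of 26) and chaperones (5 of 11) were lower in fug1, and seed storage (5 of 6) and root genes (5 of 8) higher. With an estimated correlation none of these calls held (adjusted p = 0.294 to 0.645). ICL (AT3G21720), isocitrate lyase of the glyoxylate cycle, rose by 3.11 ± 0.28, adjusted p = 2.20e-06, from 6.49 ± 2.06 to 56.0 ± 9.26 CPM. IF1 (AT4G11175), another translation initiation factor gene, fell, at -2.49 ± 0.51, adjusted p = 0.00226. The clock gene GI (AT1G22770) rose by 1.12 ± 0.20, adjusted p = 0.000948, but had -0.03 when scaled by library totals. In all 1528 genes were higher and 1211 lower, by library totals 0 and 8 (3226 unadjusted) and with the root score 27 and 3.

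Other large rises were those of the cruciferin gene CRU3 (AT4G28520; 3.73 ± 0.93), AGP3 (3.53 ± 0.69), XTH14 (3.49 ± 0.73), the phosphate transporter gene PHT1;1 (AT5G43350; 3.42 ± 0.96) and the dehydrogenase gene SDR4 (AT3G29250; 3.37 ± 0.89). Other large falls were those of cPT4 (AT5G58770), a cis-prenyltransferase (-2.82 ± 0.44, adjusted p = 0.000263), RGF9 (-2.70 ± 0.56) and FES1 (AT2G33835), a flowering regulator whose locus overlaps AT2G33840 (-2.66 ± 0.41). The ferric reductase gene FRO8 (AT5G50160) and the small peptide gene RTFL16 (AT3G25717) fell, at -2.47 ± 0.48 and -2.40 ± 0.41.

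Of 39 nuclear genes for plastid ribosomal proteins, 15 fell (16 adjusted over the list alone), such as RPL19B (AT5G47190; -1.77 ± 0.27, adjusted p = 0.000229) and emb2184 (-1.41 ± 0.23). Their median was -0.50 (camera adjusted p = 4.12e-06, estimated-correlation p = 0.645). Of 7 translation factors 4 fell (4 alone), among them IF1 and the ribosome recycling factor gene RRF (AT3G63190; -0.95 ± 0.25). Their median was -0.79 (camera adjusted p = 0.0141, estimated-correlation p = 0.514). Of 26 proteases 6 fell (10 alone), with CLP2 at -1.05 ± 0.22 and DEG5 at -1.55 ± 0.36. Their median was -0.42 (camera adjusted p = 0.000221, estimated-correlation p = 0.514). Of 11 chaperones 5 fell (5 alone), CR88 at -1.11 ± 0.25 and CPN60B (AT1G55490), whose locus overlaps ZKT, at -0.96 ± 0.27. Their median was -0.43 (camera adjusted p = 0.00238, estimated-correlation p = 0.44). Tetrapyrrole synthesis had 1 higher and 7 lower genes of 28 (1 higher and 8 lower alone). CHLI2 fell, at -1.70 ± 0.32, adjusted p = 0.00121, HEMA1 (AT1G58290), glutamyl-tRNA reductase, at -1.04 ± 0.26 and CHLI1 (AT4G18480) at -0.92 ± 0.23. Its median was -0.27 (camera adjusted p = 0.0348, estimated-correlation p = 0.841). Leaving out wild type 1, fug1 2, gun1 fug1 1 or gun1 fug1 2 ended the call (adjusted p = 0.0568, 0.0874, 0.0527 and 0.0528). It turned to 0.25 with the root score and without gun1 fug1 3 (camera adjusted p = 0.0333). Of 10 plastid-encoded NDH genes, ndhK fell (-2.22 ± 0.57; 1 alone), and ndhJ had -1.41 ± 0.47, adjusted p = 0.0603. Their median was -1.25 (camera adjusted p = 0.0134, estimated-correlation p = 0.731). It turned to 1.41 with the root score as a covariate (camera adjusted p = 1.21e-06) and 0.62 with that score and without gun1 fug1 3 (camera adjusted p = 0.000569).

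Light-harvesting proteins were higher as a set against other genes, and lower by library totals (median 0.34 and -0.83; camera adjusted p = 0.0311, estimated-correlation p = 0.862). Of 20 genes 1 rose (1 adjusted over the list alone), LHCB4.3 (AT2G40100; 0.78 ± 0.21; -0.38 by library totals), and LHCB3 (AT5G54270) had -0.75 ± 0.29, adjusted p = 0.0733. Leaving out wild type 3 or fug1 1 ended the call (adjusted p = 0.28 and 0.118), and without wild type 3 the median was 0.21. Of 8 root genes 5 rose (7 alone), SHV2 by 3.85 ± 0.64 and LRX1 (AT1G12040), a root hair wall protein, by 3.54 ± 0.90. Their median was 3.02 (camera adjusted p = 3.74e-05, estimated-correlation p = 0.304). Of 6 seed storage genes 5 rose (6 alone), CRA1 by 2.301 ± 0.30 and OLEO1 by 2.34 ± 0.35. Their median was 2.26 (camera adjusted p = 5.33e-05, estimated-correlation p = 0.294).

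Lists without a call held further genes that passed. In the photosystems 6 of 32 fell (7 adjusted over the list alone; camera adjusted p = 0.0716), such as PSAN (-1.57 ± 0.27), PSAK (AT1G30380; -1.25 ± 0.28) and FNR2 (-1.18 ± 0.27). In carbon fixation 3 of 17 fell (3 alone; camera adjusted p = 0.841; median 0.09, mean -0.10): CP12-2 (AT3G62410; -1.26 ± 0.24), SBPASE (AT3G55800; -1.08 ± 0.23) and the bisphosphatase gene HCEF1 (AT3G54050; -0.78 ± 0.24). Among 8 regulators of plastid-to-nucleus signalling TED4 (-0.78 ± 0.20), PTM (AT5G35210; -0.78 ± 0.21) and the GATA factor gene GNC (AT5G56860; -1.59 ± 0.46) fell (1 higher and 3 lower alone; camera adjusted p = 0.619). In the transcription machinery 4 of 20 fell (4 alone; camera adjusted p = 0.0714), including PTAC7 (AT5G24314; -1.45 ± 0.39), MURE (AT1G63680; -1.19 ± 0.33) and SIGA (-1.37 ± 0.36). Of 8 genes of oxidative stress 3 rose (3 alone; camera adjusted p = 0.0503): the superoxide dismutase genes CSD1 (AT1G08830; 1.45 ± 0.30) and CSD2 (AT2G28190; 0.92 ± 0.29; -0.23 by library totals), and RHL41 (AT5G59820; ZAT12; 1.93 ± 0.45). Of 8 glucosinolate genes 3 rose (3 alone; camera adjusted p = 0.561): BCAT4 (AT3G19710; 1.76 ± 0.54; 1.11, adjusted p = 0.311 without fug1 3), CYP79B2 (AT4G39950; 0.85 ± 0.24; -0.29 by library totals) and CYP83B1 (AT4G31500; 0.61 ± 0.19; -0.54 by library totals). In the clock list LHY (AT1G01060; -1.80 ± 0.52) and RVE8 (AT3G09600; -1.33 ± 0.42) fell beside the rise of GI (1 higher and 2 lower alone; camera adjusted p = 0.986; median 0.03, mean -0.24, test upward). The 8 lists left, in which at most 2 members passed, had camera adjusted p of 0.228 to 0.986, and the polymerase list differed in sign (median 0.09, mean -0.11, test downward).

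In fug1 the numbers of higher and lower genes moved likewise to 585 and 570 (wild type 1), 468 and 497 (wild type 2), 806 and 605 (fug1 1), 1009 and 662 (fug1 2) and 791 and 580 (fug1 3). Of 49 named genes called, 24 stayed called whichever 1 library was left out: ICL, cPT4, RGF9, FES1, IF1, FRO8, RTFL16, PSAN, PSAK, FNR2, CP12-2, SBPASE, CHLI2, RPL19B, emb2184, CLP2, DEG5, CR88, CSD1, RHL41, GI, SHV2, CRA1 and OLEO1. The other 25 lost the call, with adjusted p of up to 0.157 (wild type 1), 0.154 (wild type 2), 0.0635 (wild type 3), 0.0638 (gun1 2), 0.0522 (gun1 3), 0.122 (fug1 1), 0.15 (fug1 2), 0.311 (fug1 3), 0.0608 (gun1 fug1 1) and 0.0544 (gun1 fug1 2). Camera also called, without gun1 fug1 3, plastid-encoded photosynthesis genes (median 0.47, adjusted p = 0.00874), the transcription machinery (median -0.29, adjusted p = 0.0495) and oxidative stress (median 0.57, adjusted p = 0.039), at estimated-correlation p = 0.444 to 0.77.

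How far the mutants changed alike was measured across genes, which are not independent replicates. Log2 fold changes against wild type correlated at 0.84 between gun1 and fug1, 0.72 between gun1 and gun1 fug1 and 0.79 between fug1 and gun1 fug1. The same 3 wild-type libraries enter each, and simulated groups without any effect gave 0.43, 0.41 and 0.39. Covariances were 0.471, 0.494 and 0.663, and 0.0562, 0.0558 and 0.0559 in these simulations. Of called genes, 469 were higher and 302 lower in both single mutants, and independent lists would share 53.8 and 29.3. For gun1 and gun1 fug1 these were 471 and 237 (independent 64.9 and 36.8), and for fug1 and gun1 fug1 1101 and 707 (183 and 120). Simulations without effect shared at most 0.2, but call too few genes to serve as a base. Part of the excess can come from the shared wild type or a gradient, which independent lists leave out. These counts were lowest without wild type 2 (83 and 44, 92 and 39, 362 and 311) and highest without gun1 fug1 3 (795, 797 and 1529 higher) and without gun1 1 (615 and 485 lower) or wild type 3 (900). Opposite calls numbered 0, 0 and 1 in these pairs.

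The double mutant was compared with wild type to describe both mutations together. As sets, nuclear genes for plastid ribosomes (24 of 39 called) and photosystems (11 of 32) were lower against other genes, and cytosolic heat shock (3 of 3), root (6 of 8) and seed storage genes (4 of 6) higher. No such call held with an estimated correlation (adjusted p = 0.304 to 0.621). HSP90.1 (AT5G52640) and HSP70 (AT3G12580) rose by 2.47 ± 0.39, adjusted p = 0.000183 (1.58 without gun1 fug1 1), and 1.76 ± 0.29, adjusted p = 0.00041. ATPD (AT4G09650), a subunit of the plastid ATP synthase, fell from 139.8 ± 9.45 to 25.4 ± 11.7 CPM (-2.36 ± 0.32, adjusted p = 3.73e-05). In all 1843 genes were higher and 1519 lower, by library totals 43 and 131 and with the root score 126 and 56.

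Falls were largest for the small peptide gene RTFL18 (AT5G16023; -4.66 ± 0.62, adjusted p = 2.62e-05), the auxin-responsive SAUR29 (AT3G03820; -3.19 ± 0.44) and GASA6 (AT1G74670), a gibberellin-regulated peptide gene (-3.13 ± 0.27). The calmodulin gene CAM5 (AT2G27030; -2.91 ± 0.35), the light signalling gene HFR1 (AT1G02340; -2.89 ± 0.34) and ESM1 (AT3G14210), which modifies glucosinolate breakdown (-2.86 ± 0.34), followed. Rises were largest for RR3, a response regulator gene (8.30 ± 2.01), the xylosidase gene BXL3 (AT5G09730; 7.92 ± 1.90) and the U2 small nuclear RNA genes U2.7 (AT5G61455; 8.59 ± 2.31), U2.4 (AT3G56825; 8.13 ± 2.13), U2.3 (AT3G57765; 8.07 ± 2.12) and U2.5 (AT5G09585; 7.91 ± 2.05). Without gun1 fug1 3 these rises were smaller and still called (2.88, 3.07, 2.70, 3.33, 2.77 and 2.79 in that order, adjusted p = 2.30e-06 to 0.013). The loci of RR3, U2.4 and U2.3 overlap AT2G09250, AT3G56820 and AT3G57770.

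Of 39 nuclear genes for plastid ribosomal proteins 24 fell (27 adjusted over the list alone), including PSRP3/1 (AT1G68590; -2.06 ± 0.29, adjusted p = 4.98e-05) and GHS1 (AT3G27160; RPS21; -1.62 ± 0.26). Their median was -0.77 (camera adjusted p = 4.43e-07, estimated-correlation p = 0.607). Of 32 photosystem and electron transport genes 11 fell (13 alone), PSAN at -1.95 ± 0.28, adjusted p = 4.19e-05. Their median was -0.61 (camera adjusted p = 2.53e-05, estimated-correlation p = 0.621). The proteases had 1 higher and 6 lower of 26 (1 higher and 7 lower alone), with CLPP4 (AT5G45390) at -1.30 ± 0.21, CLPP6 (AT1G11750) at -1.01 ± 0.23 and CLPS1 (AT1G68660) at -0.81 ± 0.22. Their median was -0.40 (camera adjusted p = 0.0224, estimated-correlation p = 0.691). Leaving out gun1 fug1 1 or gun1 fug1 2 ended the call (adjusted p = 0.0506 and 0.134). The 3 tested heat shock genes rose (3 alone). Their median was 1.76 (camera adjusted p = 0.00183, estimated-correlation p = 0.304). Without any 1 library but gun1 fug1 1 or 2 it was 3.17 (wild type 1) to 3.69 (wild type 3). More members then passed the filter, which may select for this rise. Of 8 root genes 6 rose (7 alone), SHV2 by 4.52 ± 0.61 and PRP1 (AT1G54970) by 3.78 ± 0.76. Their median was 3.97 (camera adjusted p = 0.000216, estimated-correlation p = 0.353). Of 6 seed storage genes 4 rose (5 alone), CRA1 by 3.56 ± 0.31, adjusted p = 2.04e-07 and OLEO1 by 2.11 ± 0.37. Their median was 2.39 (camera adjusted p = 0.000868, estimated-correlation p = 0.33). Of 17 plastid-encoded ribosomal protein genes 5 rose against other genes, not by library totals (9 alone), with rps19 (ATCG00820) at 1.94 ± 0.27 and rps16 (ATCG00050) at 3.82 ± 0.89 (2.38 without gun1 fug1 3). Their median was 2.49, and -0.22 by library totals (camera adjusted p = 0.000216, estimated-correlation p = 0.673). Leaving out gun1 fug1 3 ended the call (median 0.74, adjusted p = 0.0761).

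Further genes passed in lists without a call. In the clock list GI (1.65 ± 0.21, adjusted p = 1.02e-05) and TOC1 (AT5G61380; 1.08 ± 0.32; -0.15 by library totals) rose and RVE8 (-1.65 ± 0.47) fell, in all 3 higher and 2 lower of 11 (5 higher and 2 lower adjusted over the list alone; camera adjusted p = 0.236). Tetrapyrrole synthesis had 2 higher and 5 lower of 28 (3 higher and 6 lower alone; camera adjusted p = 0.298), with CHLI1 at -1.16 ± 0.24, CHLI2 at -1.47 ± 0.33 and TED4 at -0.83 ± 0.22. The signalling regulators had 1 higher and 3 lower of 8 (2 higher and 3 lower alone; camera adjusted p = 0.722), with PTM at -0.74 ± 0.23 and GNC at -1.36 ± 0.47 (-2.05 without gun1 fug1 1). In the transcription machinery PTAC12 (AT2G34640), whose locus overlaps GPS1, rose (1.78 ± 0.54), and PTAC7 (-1.20 ± 0.40) and SIGE (-1.37 ± 0.48; -2.27 without gun1 fug1 1, and -0.91, adjusted p = 0.275 without gun1 fug1 2) fell (0 alone; camera adjusted p = 0.561). Plastid-encoded photosynthesis genes went both ways, with 5 higher and 3 lower of 33 (6 higher and 3 lower alone; camera adjusted p = 0.565). Among them psaA (ATCG00350) fell (-1.96 ± 0.42), while psbA (ATCG00020; 3.56 ± 0.86; 1.06 without gun1 fug1 3) and psbC (ATCG00280; 2.13 ± 0.58; 0.59 without gun1 fug1 3 and -0.32 by library totals) rose. Without gun1 fug1 3 that list had 3 higher and 16 lower members and a median of -1.03 in place of 0.74 (camera adjusted p = 0.00025, estimated-correlation p = 0.638). Chaperones (median -0.10, mean 0.05, test upward) and light-harvesting proteins (-0.09, -0.06, upward) differed in sign, and the 12 other lists had camera adjusted p of 0.0913 to 0.911.

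Against wild type the gene numbers of gun1 fug1 moved to 986 and 1008 (wild type 1), 928 and 976 (wild type 2), 1129 and 781 (gun1 fug1 1) and 1034 and 708 (gun1 fug1 2). Of 41 named genes called, 17 lost the call without at least 1 library, with adjusted p of up to 0.123 (wild type 1), 0.124 (wild type 2), 0.0859 (wild type 3), 0.0667 (gun1 2), 0.0642 (fug1 1), 0.0653 (fug1 2), 0.052 (fug1 3), 0.216 (gun1 fug1 1), 0.275 (gun1 fug1 2) and 0.0833 (gun1 fug1 3): U2.7, RR3, U2.4, U2.3, BXL3, U2.5, TED4, PTM, GNC, PTAC12, PTAC7, SIGE, CLPS1, psbC, rps16, RVE8 and TOC1. Without gun1 fug1 3 camera also called NDH genes (median -2.24, adjusted p = 0.000152) and oxidative stress (median 0.52, adjusted p = 0.0104), at estimated-correlation p = 0.387 to 0.556.

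**Figure D3:**
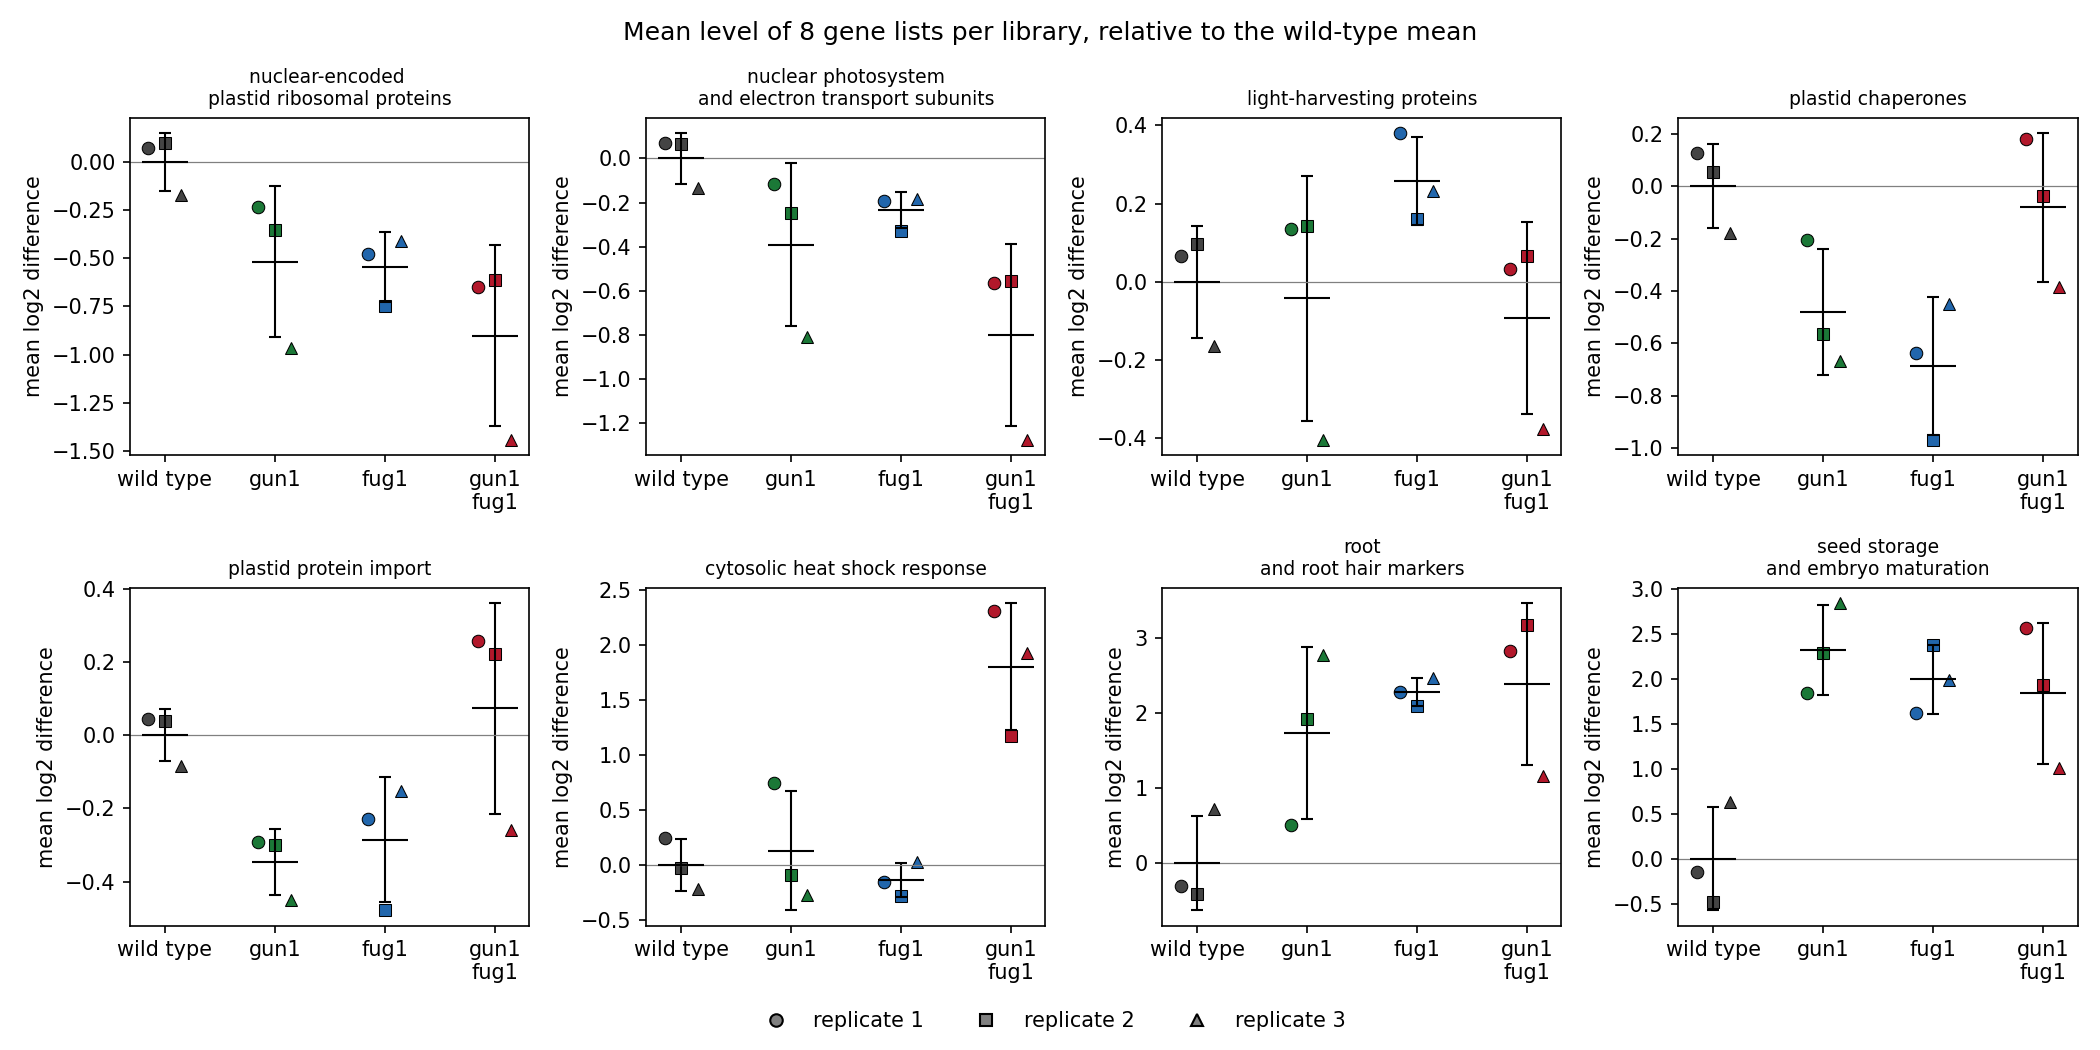
Mean log2 level of the tested members of 8 gene lists relative to the wild-type mean, by genotype; points are libraries, bars means and error bars SD. Root genes average 1.73, 2.28 and 2.39 in gun1, fug1 and gun1 fug1, and seed storage genes 2.32, 1.99 and 1.84.

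Comparing gun1 fug1 with fug1 asks what the gun1 mutation adds to fug1. Plastid chaperones (4 of 11 called) and cytosolic heat shock genes (2 of 3) were higher as sets against other genes in gun1 fug1, but not with an estimated correlation (adjusted p = 0.304 and 0.294). Cpn60beta2 (AT3G13470), a subunit of the plastid chaperonin, stood at 23.8 ± 7.48 CPM in gun1 fug1 and 8.56 ± 0.825 in fug1 (1.58 ± 0.24, adjusted p = 0.00123). HSP90.1 rose by 2.68 ± 0.44, adjusted p = 0.00649 (1.77, adjusted p = 0.289 without gun1 fug1 1), and GolS1 (AT2G47180), a galactinol synthase gene whose locus overlaps ARF1A1C, by 2.08 ± 0.25, adjusted p = 0.000175. In all 25 genes were higher and 16 lower, by library totals 1 and 0 (112 unadjusted) and with the root score 143 and 109.

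CSD2 rose by 1.98 ± 0.28, adjusted p = 0.000835. The largest falls beside GUN1 were those of CKX5 (AT1G75450), a cytokinin oxidase gene whose locus overlaps UBC16 (-2.36 ± 0.35, adjusted p = 0.00122), and PAR1 (AT2G42870) of the shade response (-1.64 ± 0.27). Of 11 chaperones 4 rose (6 adjusted over the list alone), CR88 by 1.43 ± 0.27. Their median was 0.54 (camera adjusted p = 8.45e-05, estimated-correlation p = 0.304), and 0.83 without fug1 1, 0.88 without fug1 3 and 0.84 without gun1 fug1 3. Of 3 heat shock genes 2 rose (3 alone), HSP70 by 1.67 ± 0.30. Their median was 1.84 (camera adjusted p = 2.42e-05, estimated-correlation p = 0.294). Over more members it was 4.43 without fug1 3. Of 7 translation factors emb2726 (AT4G29060; EF-Ts) rose by 1.13 ± 0.25 (2 alone), and SCO1 had 0.76 ± 0.27, adjusted p = 0.259. Their median was 0.65 (camera adjusted p = 0.0157, estimated-correlation p = 0.519). Leaving out gun1 fug1 1 ended the call (adjusted p = 0.0543). Further lists were called without a member that passed by edgeR, which left 1741 genes at an unadjusted p under 0.05. Import genes had TIC110 (AT1G06950) at 0.82 ± 0.20 and emb1211 at 0.90 ± 0.24 (5 alone). Their median was 0.55 (camera adjusted p = 0.00063, estimated-correlation p = 0.294). The transcription machinery had SIGF (AT2G36990) at 0.81 ± 0.29 and PTAC12 at 1.49 ± 0.59. Its median was 0.48 (camera adjusted p = 0.0021, estimated-correlation p = 0.294). Clock genes had GI at 0.53 ± 0.21 and PRR7 (AT5G02810) at 0.62 ± 0.32. Their median was 0.53 (camera adjusted p = 0.0466, estimated-correlation p = 0.304). Leaving out gun1 2, fug1 1, fug1 3, gun1 fug1 1 or gun1 fug1 2 ended the call (adjusted p = 0.0524, 0.0561, 0.118, 0.0703 and 0.15). Light-harvesting proteins had LHCB2.3 (AT3G27690) at -0.83 ± 0.28 and CAB3 (AT1G29910) at -0.78 ± 0.28. Their median was -0.28 (camera adjusted p = 0.0313, estimated-correlation p = 0.862), and -0.18 without gun1 fug1 3. Leaving out fug1 1, gun1 fug1 1 or gun1 fug1 2 ended the call (adjusted p = 0.137, 0.111 and 0.0958).

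Against fug1 the photosystem genes, with ATPD at -1.17 ± 0.31 and PSBTN (AT3G21055) at -0.96 ± 0.30, were lower as a set, and 0 passed (7 adjusted over the list alone). Their median was -0.44 (camera adjusted p = 0.00011, estimated-correlation p = 0.673). So were nuclear genes for plastid ribosomal proteins, with PSRP3/1 at -0.81 ± 0.31 and RPS1 (AT5G30510) at -0.54 ± 0.22. Their median was -0.30 (camera adjusted p = 0.0459, estimated-correlation p = 0.957), and -0.10 without gun1 fug1 3. Leaving out fug1 1, fug1 3, gun1 fug1 1, gun1 fug1 2 or gun1 fug1 3 ended the call (adjusted p = 0.123, 0.213, 0.0647, 0.0511 and 0.261). Plastid-encoded ribosomal protein genes, with rps19 at 0.80 ± 0.27 and rps16 at 2.50 ± 0.85, were higher as a set. Their median was 2.40 (camera adjusted p = 1.23e-06, estimated-correlation p = 0.558). Leaving out gun1 fug1 3 ended the call (median 0.28, adjusted p = 0.231). Genes read by the nuclear-encoded polymerase, with rpoB (ATCG00190) at 2.69 ± 0.94 and rpoC1 at 2.72 ± 0.98, were higher too. Their median was 2.27 (camera adjusted p = 0.0206, estimated-correlation p = 0.673). Leaving out gun1 fug1 3 ended the call (median 0.26, adjusted p = 0.887). The 13 other lists had camera adjusted p of 0.207 to 0.958, among them root and seed storage genes (medians 0.71 and 0.08). Plastid-encoded photosynthesis genes (median 0.51, mean 0.64, test downward), oxidative stress (0.01, 0.02, downward) and the regulators (0.00, -0.03, upward) differed in sign.

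Against fug1 the gene numbers moved to 36 and 32 (gun1 3), 12 and 8 (fug1 1), 11 and 12 (fug1 2), 11 and 9 (fug1 3), 12 and 5 (gun1 fug1 1) and 59 and 57 (gun1 fug1 3). Of 9 named genes called, 4 stayed called whichever 1 library was left out: GolS1, CSD2, CKX5 and Cpn60beta2. The other 5 lost the call, with adjusted p of up to 0.0531 (wild type 1), 0.0985 (wild type 2), 0.0883 (gun1 2), 0.245 (fug1 1), 0.216 (fug1 2), 0.125 (fug1 3), 0.4 (gun1 fug1 1) and 0.088 (gun1 fug1 2). Camera also called, without gun1 fug1 3, plastid-encoded photosynthesis genes (median -1.17, adjusted p = 6.07e-23), NDH genes (median -0.75, adjusted p = 0.00731) and dividing cells (median -0.84, adjusted p = 0.0289), at estimated-correlation p = 0.282 to 0.638.

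Comparing gun1 fug1 with gun1 asks what the fug1 mutation adds to gun1. Import (4 of 10 called), chaperone (4 of 11) and heat shock genes (2 of 3) were higher as sets against other genes in gun1 fug1, and photosystem genes (1 of 32) lower. These calls ended with an estimated correlation (adjusted p = 0.294 to 0.904). Cpn60beta2 stood at 9.18 ± 2.15 CPM in gun1 (1.47 ± 0.23, adjusted p = 0.000902), and TIC56 of the import translocon rose by 1.13 ± 0.22, adjusted p = 0.00584. EXT4 (AT1G76930), a cell wall extensin gene, rose by 2.59 ± 0.35, adjusted p = 0.000176, HSP90.1 by 2.60 ± 0.41 (1.70, adjusted p = 0.0955 without gun1 fug1 1) and rps16 by 4.84 ± 0.94. The largest falls were those of CKX5, ESM1 and GASA6, at -2.61 ± 0.34, adjusted p = 0.000176, -2.51 ± 0.34 and -2.30 ± 0.26. In all 248 genes were higher and 227 lower, by library totals 3 and 2 and with the root score 396 and 257.

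Of 10 import genes 4 rose (6 adjusted over the list alone), TIC110 by 0.99 ± 0.20. Their median was 0.61 (camera adjusted p = 0.00023, estimated-correlation p = 0.294). Of 11 chaperones 4 rose against other genes (4 alone), cpHsc70-1 (AT4G24280) by 1.06 ± 0.20, adjusted p = 0.00584. Their median was 0.43, and -0.11 by library totals (camera adjusted p = 0.00362, estimated-correlation p = 0.477). The median was 0.07 without gun1 fug1 1. Of 3 heat shock genes 2 rose (3 alone), HSP70 by 1.27 ± 0.29 (0.79, adjusted p = 0.229 without gun1 fug1 1). Their median was 1.34 (camera adjusted p = 0.00028, estimated-correlation p = 0.294). Without any 1 library but gun1 fug1 1 or 2 it was 2.39 (gun1 3) to 2.97 (gun1 2), over more members. Of 7 translation factors emb2726 rose by 1.35 ± 0.25, adjusted p = 0.00426 (2 alone), and SCO1 had 0.83 ± 0.27, adjusted p = 0.0807. Their median was 0.50, and -0.07 by library totals (camera adjusted p = 0.0199, estimated-correlation p = 0.526). The median was 0.85 without gun1 1 and 0.26 without gun1 3. Leaving out gun1 3 or gun1 fug1 1 ended the call (adjusted p = 0.168 and 0.0527). No gene of the transcription machinery passed (3 alone), with PDE312 (AT3G48500; PTAC10) at 1.38 ± 0.45 and RPOTMP (AT5G15700) at 1.75 ± 0.58. Its median was 0.57, and -0.02 by library totals (camera adjusted p = 0.00102, estimated-correlation p = 0.294). The median was 0.33 without gun1 fug1 1. Of 17 plastid-encoded ribosomal protein genes 2 rose (14 alone), rps19 by 2.12 ± 0.27. Their median was 3.62 (camera adjusted p = 6.67e-13, estimated-correlation p = 0.357), and 1.46 without gun1 fug1 3. None of the nuclear-encoded polymerase's genes passed (4 alone), with rpoB at 4.18 ± 1.00 and rpoC1 at 3.47 ± 1.01. Their median was 3.02 (camera adjusted p = 0.000291, estimated-correlation p = 0.514), and 1.13 without gun1 fug1 3. Of 32 photosystem genes ATPD fell, at -1.59 ± 0.31, adjusted p = 0.00827 (3 alone), and PSAN had -0.85 ± 0.27, adjusted p = 0.0794. Their median was -0.31 (camera adjusted p = 0.0348, estimated-correlation p = 0.904), and -0.17 without gun1 fug1 3 and -0.52 without gun1 3. Leaving out gun1 1, gun1 2, gun1 fug1 1, gun1 fug1 2 or gun1 fug1 3 ended the call (adjusted p = 0.271, 0.147, 0.0555, 0.0528 and 0.144). No nuclear gene for a plastid ribosomal protein passed (4 alone), with PSRP3/1 at -1.02 ± 0.30 and RPS1 at -0.73 ± 0.22. Their median was -0.29 (camera adjusted p = 0.0446, estimated-correlation p = 0.957), and -0.15 without gun1 1 and -0.50 without gun1 3. Leaving out gun1 1, gun1 2, gun1 fug1 1 or gun1 fug1 3 ended the call (adjusted p = 0.335, 0.223, 0.0596 and 0.343). It turned to 0.20 with the root score and without gun1 fug1 3 (camera adjusted p = 0.0361). The 15 other lists had camera adjusted p of 0.0515 to 0.911, among them root and seed storage genes (medians 0.98 and -0.45). Signs of median, mean and test differed for light-harvesting proteins (-0.08, -0.04, upward), proteases (-0.05, -0.02, upward), cold response (-0.16, 0.01, upward), carbon fixation (0.02, -0.08, upward) and the regulators (0.04, -0.03, upward).

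Against gun1 the gene numbers moved to 160 and 162 (wild type 2), 107 and 84 (gun1 1), 77 and 63 (gun1 2), 306 and 376 (gun1 3), 55 and 41 (gun1 fug1 1), 139 and 94 (gun1 fug1 2) and 481 and 339 (gun1 fug1 3). Of 14 named genes called, 7 stayed called whichever 1 library was left out: EXT4, CKX5, ESM1, GASA6, ATPD, Cpn60beta2 and rps19. The other 7 lost the call, with adjusted p of up to 0.0516 (wild type 1), 0.0589 (wild type 2), 0.0887 (gun1 1), 0.136 (gun1 2), 0.0766 (gun1 3), 0.0526 (fug1 2), 0.0548 (fug1 3) and 0.229 (gun1 fug1 1). Camera also called, without gun1 fug1 3, plastid-encoded photosynthesis genes (median -0.80, adjusted p = 2.54e-06), tetrapyrrole synthesis (median 0.10, adjusted p = 0.0339), oxidative stress (median 0.53, adjusted p = 0.0251), the clock (median 0.54, adjusted p = 0.0227), root genes (median 1.04, adjusted p = 0.00989) and dividing cells (median -0.76, adjusted p = 0.0179), at estimated-correlation p = 0.297 to 0.77.

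**Figure D4:**
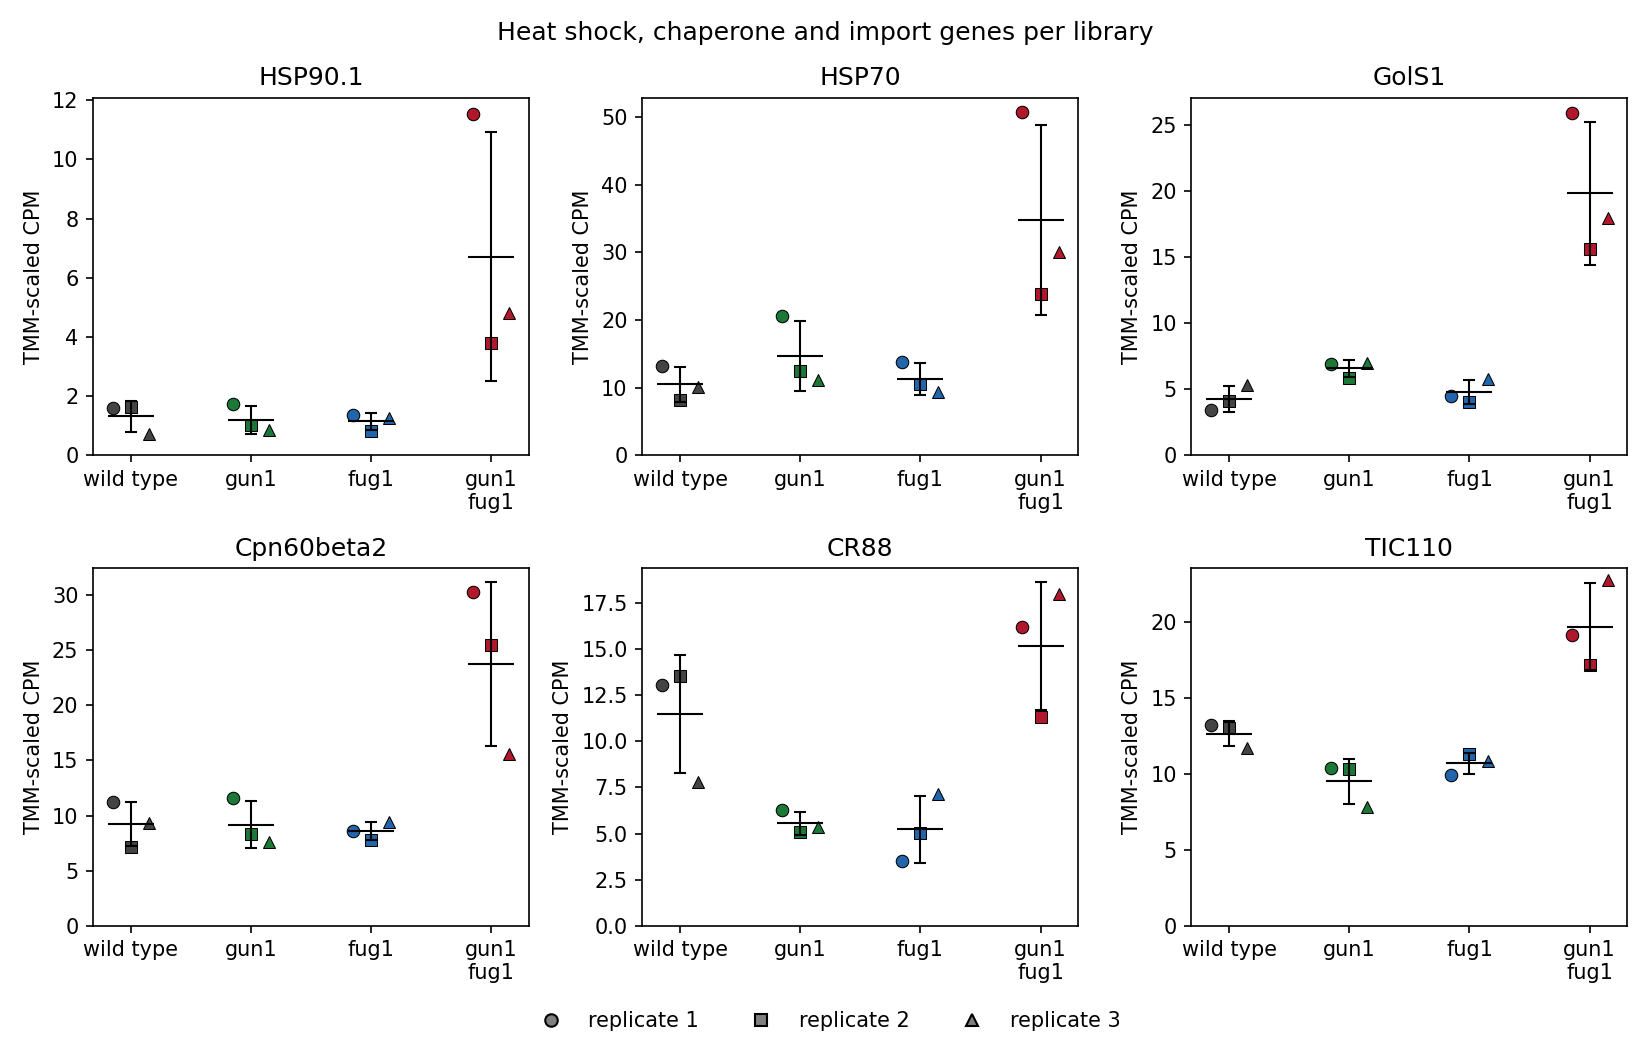
Levels (normalised CPM) of 6 chaperone, heat shock and import genes by genotype; points are libraries, bars means and error bars SD. Cpn60beta2 averages 23.8 CPM in gun1 fug1 against 8.56 in fug1 and 9.18 in gun1.

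The interaction asks whether gun1 fug1 differs from the sum of the single mutant effects on the log2 scale. As sets against other genes, plastid chaperones (4 of 11 called), translation factors (3 of 7) and import genes (3 of 10) lay above that sum, and seed storage genes (1 of 6) below it. Here too no call held with an estimated correlation (adjusted p = 0.294 to 0.304). CR88 fell in both single mutants, yet stood at 15.2 ± 3.45 CPM in gun1 fug1 and 11.5 ± 3.19 in wild type (2.48 ± 0.36, adjusted p = 0.00208). OLEO1, which rose in each single mutant, lay -2.68 ± 0.49, adjusted p = 0.00907 from the sum. In all 123 genes lay above it and 83 below, by library totals 0 and 0 (315 unadjusted) and with the root score 49 and 39.

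Largest above the sum were SKIP5 (4.35 ± 0.64, adjusted p = 0.00208), nearly lost in gun1 only, cPT4 (2.95 ± 0.66) and ATSPS4F (AT4G10120), a sucrose phosphate synthase gene overlapping AT4G10130 (2.90 ± 0.61). Largest below were LTP4 (AT5G59310), a lipid transfer protein gene (-3.68 ± 0.58, adjusted p = 0.0036), RTFL18 (-3.28 ± 0.80) and SQP2 (-3.25 ± 0.68). Of 11 chaperones 4 lay above (8 adjusted over the list alone), CPN60B by 2.38 ± 0.39, adjusted p = 0.00562. Their median was 1.31 (camera adjusted p = 4.84e-06, estimated-correlation p = 0.294). Of 7 translation factors 3 lay above (6 alone), emb2726 by 1.82 ± 0.34 and SCO1 by 1.62 ± 0.37. Their median was 1.45 (camera adjusted p = 8.67e-05, estimated-correlation p = 0.304). Of 10 import genes 3 lay above (5 alone), TIC56 by 1.46 ± 0.30 and emb1211 by 1.48 ± 0.32. Their median was 0.97 (camera adjusted p = 0.00011, estimated-correlation p = 0.294). Of 3 heat shock genes HSP90.1 lay above by 2.81 ± 0.63, adjusted p = 0.0296 (3 alone), and HSP70 had 1.19 ± 0.41, adjusted p = 0.139. Their median was 1.64 (camera adjusted p = 0.00107, estimated-correlation p = 0.297). Over more members it was 3.95 without fug1 3 and 2.73 without gun1 1. In tetrapyrrole synthesis HEMA1 lay above by 1.68 ± 0.36 (3 alone), and ALB1 (AT1G08520; CHLD) had 1.04 ± 0.27, adjusted p = 0.0511. Its median was 0.39 (camera adjusted p = 0.000898, estimated-correlation p = 0.621), and 0.26 without gun1 3. Nuclear genes for plastid ribosomal proteins had 2 of 39 above (5 alone), RPL19A (AT4G17560) by 1.63 ± 0.39 and RPL24 by 1.65 ± 0.39. Their median was 0.18 (camera adjusted p = 0.0224, estimated-correlation p = 0.934). The median was 0.11 without fug1 2, 0.08 without gun1 fug1 1, 0.09 without gun1 fug1 2, 0.28 without gun1 fug1 3, 0.32 without gun1 1, -0.05 without gun1 3 and 0.11 without wild type 1. Leaving out wild type 2, gun1 3, fug1 2, gun1 fug1 1 or gun1 fug1 2 ended the call (adjusted p = 0.0694, 0.608, 0.15, 0.106 and 0.18). Of 6 seed storage genes OLEO1 lay below (5 alone), and CRA1 had -1.57 ± 0.40, adjusted p = 0.0511. Their median was -2.41 (camera adjusted p = 0.000259, estimated-correlation p = 0.304).

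Other lists were called in the interaction without a member that passed by edgeR, which left 2866 genes at an unadjusted p under 0.05. The transcription machinery had SIGA at 2.104 ± 0.53 and SIG2 (AT1G08540) at 1.24 ± 0.36 (5 adjusted over the list alone). Its median was 1.16 (camera adjusted p = 2.86e-05, estimated-correlation p = 0.294), and 0.72 without gun1 fug1 1. The proteases had FTSH12 (AT1G79560), whose locus overlaps PGK, at 1.61 ± 0.43 and CLPC1 (AT5G50920) at 1.19 ± 0.35 (5 alone). Their median was 0.35 (camera adjusted p = 0.00152, estimated-correlation p = 0.558). Plastid-encoded NDH genes had ndhK at 2.58 ± 0.80 and ndhC (ATCG00440) at 4.01 ± 1.34. Their median was 1.94 (camera adjusted p = 0.000259, estimated-correlation p = 0.581). Leaving out gun1 fug1 3 ended the call (median 0.87, adjusted p = 0.102). Plastid-encoded ribosomal protein genes had rpl32 at 6.33 ± 1.77 and rps2 at 2.75 ± 0.87 (10 alone). Their median was 3.14 (camera adjusted p = 5.38e-09, estimated-correlation p = 0.514), and 1.65 without gun1 fug1 3. Genes of the nuclear-encoded polymerase had rpoC1 at 4.25 ± 1.35 and accD at 3.46 ± 1.27 (4 alone). Their median was 3.46 (camera adjusted p = 0.00242, estimated-correlation p = 0.558), and 1.24 without gun1 fug1 3. Root genes lay below as a set, with SHV2 at -3.12 ± 0.81 and SHR (AT4G37650) at -1.02 ± 0.37 (2 alone). Their median was -1.96 (camera adjusted p = 0.0298, estimated-correlation p = 0.607), and -1.12 without gun1 3. Leaving out gun1 3, gun1 fug1 1 or gun1 fug1 3 ended the call (adjusted p = 0.0757, 0.0555 and 0.0787). The 11 other lists had camera adjusted p of 0.0563 to 0.986, and carbon fixation (median -0.04, mean 0.02, test upward), cold response (-0.18, 0.11, upward) and dividing cells (-0.65, -0.55, upward) differed in sign.

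In the interaction the numbers above and below the sum moved to 23 and 12 (wild type 1), 18 and 11 (wild type 2), 297 and 223 (wild type 3), 385 and 305 (gun1 1), 24 and 19 (gun1 2), 54 and 37 (gun1 3), 27 and 16 (fug1 1), 28 and 24 (fug1 2), 33 and 23 (fug1 3), 13 and 15 (gun1 fug1 1), 106 and 50 (gun1 fug1 2) and 255 and 177 (gun1 fug1 3). Of 17 named genes called, 5 stayed called whichever 1 library was left out: SKIP5, LTP4, CR88, CPN60B and OLEO1. The other 12 lost the call, with adjusted p of up to 0.115 (wild type 1), 0.129 (wild type 2), 0.111 (gun1 2), 0.0804 (gun1 3), 0.108 (fug1 1), 0.109 (fug1 2), 0.0889 (fug1 3), 0.249 (gun1 fug1 1), 0.073 (gun1 fug1 2) and 0.0543 (gun1 fug1 3). Camera also called, without gun1 fug1 3, plastid-encoded photosynthesis genes (median -1.28, adjusted p = 3.04e-09), at estimated-correlation p = 0.476.

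Changes are relative to the bulk of genes. By library totals alone, the median log2 fold change of all genes was -0.54 in gun1, -1.16 in fug1 and -1.17 in gun1 fug1 against wild type, 0.02 against fug1, -0.59 against gun1 and 0.50 in the interaction, where the scaling used gave values within 0.081 of 0.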

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

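The tests of the label of gun1 fug1 3 by GUN1, of replicate pairs after thinning, of the root score on seed storage genes and of the chaperone genes were chosen only after the results were seen.

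The interaction called 123 genes above and 83 below the summed single mutant effects (13 to 385 and 11 to 305 without 1 library). A shift of all mutants, whatever its cause, enters this contrast with opposite sign. So calls alone do not show that the gun1 effect depends on fug1. Of 100 regroupings of the 12 libraries, the real one included, 2 gave as many as 206 (highest other 452). Since regroupings carry the genotype effects into the contrast or the spread, they neither exclude chance nor tell genotype from another structure of the samples. Above the sum, list medians were 3.46 for nuclear-polymerase genes, 3.14 for plastid-encoded ribosomal proteins, 1.94 for NDH genes, 1.64 for heat shock, 1.45 for translation factors, 1.31 for chaperones, 1.16 for transcription, 0.97 for import, 0.39 for tetrapyrroles, 0.35 for proteases and 0.18 for nuclear genes of plastid ribosomal proteins. Below it were seed storage (-2.41) and root markers (-1.96). Without gun1 fug1 3 the first 3 medians were 1.24, 1.65 and 0.87, without gun1 fug1 1 transcription had 0.72, and without gun1 3 tetrapyrroles had 0.26, root markers -1.12 and nuclear genes of plastid ribosomal proteins -0.053 (0.079 to 0.32 without others). Over more members, heat shock had 3.95 without fug1 3 and 2.73 without gun1 1. With an estimated correlation none of these lists passed (adjusted p = 0.294 to 0.934).

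Genes above the sum were SKIP5 (4.35), cPT4 (2.95), ATSPS4F (2.90), HSP90.1 (2.81), CR88 (2.48), CPN60B (2.38), emb2726 (1.82), HEMA1 (1.68), RPL24 (1.65), RPL19A (1.63), SCO1 (1.62), emb1211 (1.48) and TIC56 (1.46). Below it were LTP4 (-3.68), RTFL18 (-3.28), SQP2 (-3.25) and OLEO1 (-2.68).

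The library gun1 fug1 3 stood apart from the other 11. Few reads left beside abundant RNAs are not the whole cause: thinned to its depth over the less abundant nuclear genes, gun1 fug1 1 and 2 correlated with it at 0.679 and 0.674, by 0.0974 less than with each other, and the 10 pairs of replicates without it correlated at 0.741 to 0.777. Thinning takes reads as separate molecules, so few molecules before amplification stay open. In gun1 fug1 3, GUN1 had 7 counts and a 95% upper limit of 17.3 CPM, below the 24.6 CPM or more of wild type and fug1. This limit too takes reads as separate molecules and rests on the scaling, so no wrong label is excluded. Other faults of this library's RNA or preparation, or a real difference of these seedlings, stay open, untested.

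As sets, root (1, 5 and 6 of 8 called in gun1, fug1 and gun1 fug1) and seed storage genes (5, 5 and 4 of 6) were higher in the mutants than in wild type, but not with an estimated correlation (adjusted p = 0.294 to 0.353). A gradient between libraries that also runs within 1 genotype may be part of the cause: across genes of neither list, gun1 3 minus gun1 1 correlated (genes are not independent replicates) with the fug1 fold change at r = 0.557 (0.396 and 0.284 for the other gun1 pairs and 0.182 for gun1 fug1 2 minus 1). With the root score as a covariate, the seed storage median in fug1 went from 2.26 to 1.22, and since the score follows the genotypes, that gradient and a genotype effect cannot be told apart here. The amount of root sampled, the stage of the seedlings and an effect of genotype all stay open, untested.

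Plastid chaperone and import genes lay above the sum as sets (only the former tested here). The chaperone call did not rest on gun1 fug1 3 alone (camera adjusted p = 6.12e-08 without it). It held with the root score as a covariate (4.85e-07), which follows the genotypes and cannot exclude a gradient. With an estimated correlation both had 0.294, the highest for chaperones in any setting, so the calls assume nearly independent genes. Genotype and another structure of the samples both stay open, untested.

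The other comparisons each had 10 splits of 6 libraries into 3 and 3, too few for a share under 0.05. Only the real 1 gave as many genes. Other splits mix the genotypes and so put their effect into the spread, which alone can lower the numbers. The real and highest other numbers were 913 and 61 for gun1, 2739 and 0 for fug1, 3362 and 17 for gun1 fug1, 41 and 0 for gun1 fug1 against fug1, and 475 and 122 against gun1.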

How the results depend on the processing

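Alternatives chosen after seeing the data were scaling by library totals, the root score as a covariate, the 2 settings that also leave out gun1 fug1 3, leaving out genes nearly equal to an overlapping locus, and leaving psbA or the most abundant mitochondrial gene out of all counts.

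With 3 libraries a group, most changes of 2-fold or less fall below what the test can call (17.2% to 29.2% recovered in simulation, 1.5% for the interaction). Intervals and limits from counts cover counting error only. What caused the movements was not tested, except where fewer libraries, fewer genes or a stricter threshold lower a number by construction. All 12 numbers of called genes stayed within 1.5 times with RLE or upper-quartile factors, and with organelle genes or genes near an overlapping locus left out. Of 62 list calls, 61 held with RLE factors and with the replicate block, all 50 that could be tested held with organelle genes left out, and 51 to 61 held without each library. By library totals 49 held, 8 were lost and 5 reversed, with the root score 30, 25 and 7, and with the root score and without gun1 fug1 3 27, 20 and 15. With fry 11 held, and with an estimated correlation 0. The root score follows the genotypes, so that it also removes differences between them. Pairing by replicate number stays open: 3 of 18 same-number pairs (-0.08 to 0.36) and 3 of 36 others correlated over 0.1. Of 12 libraries 0 matched their own number best in every other group. Of 208 values of named genes, 205 kept direction and side of the threshold with RLE, 206 with upper-quartile factors, 186 with the block, 184 with limma-voom, 142 to 192 without each library, 85 with the root score and 65 by library totals. The strict filter and DESeq2 did not test some named genes. The interaction needs 4 groups and had no fit of the compared groups alone.

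At an adjusted p under 0.01, 156 and 73 in gun1, 566 and 414 in fug1, 893 and 622 in gun1 fug1, 9 and 6 in D/fug1, 60 and 38 in D/gun1 and 14 and 9 in the interaction were called (higher and lower, D/fug1 and D/gun1 being gun1 fug1 against these). With a log2 fold change of at least 1 required: 244 lower in gun1 and 881 higher in fug1. With the replicate block: 581 lower in gun1, 40 and 46 in D/fug1, 384 and 414 in D/gun1 and 129 lower in the interaction. With DESeq2: 240 lower in gun1 and 47 lower in D/fug1. With limma-voom: 8 and 8 in D/fug1, 132 lower in D/gun1 and 56 and 37 in the interaction. With no filter on low counts: 680 lower in gun1, 92 and 65 in D/fug1, 403 and 391 in D/gun1 and 353 and 281 in the interaction. With the stricter filter: 225 higher in gun1, 759 higher in fug1, 971 higher in gun1 fug1 and 51 lower in the interaction. By library totals: 0 and 1 in gun1, 0 and 8 in fug1, 43 and 131 in gun1 fug1, 1 and 0 in D/fug1, 3 and 2 in D/gun1 and 0 and 0 in the interaction. With the root score as a covariate: 11 and 8 in gun1, 27 and 3 in fug1, 126 and 56 in gun1 fug1, 143 and 109 in D/fug1, 396 higher in D/gun1 and 49 and 39 in the interaction. With the root score and without gun1 fug1 3: 42 and 11 in gun1, 118 and 14 in fug1, 197 and 64 in gun1 fug1, 317 and 197 in D/fug1, 629 higher in D/gun1 and 200 and 183 in the interaction. With the block and without gun1 fug1 3: 1348 and 1112 in gun1, 2456 and 1931 in fug1, 2829 and 2334 in gun1 fug1, 165 and 180 in D/fug1, 859 and 697 in D/gun1 and 407 and 335 in the interaction. With only the compared groups fitted: 1873 lower in fug1 and 17 and 15 in D/gun1.

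Without each library in turn, called genes were 101 to 939 higher and 53 to 814 lower in gun1, 468 to 2131 higher and 497 to 1583 lower in fug1, 928 to 2349 higher and 708 to 1808 lower in gun1 fug1, 11 to 59 higher and 5 to 57 lower in D/fug1, 55 to 481 higher and 41 to 376 lower in D/gun1 and 13 to 385 higher and 11 to 305 lower in the interaction. FUG1 in D/fug1 ranged from -0.022 to 0.41, GUN1 in D/gun1 from -0.097 to 0.23, and nuclear genes of plastid ribosomal proteins in the interaction from -0.053 to 0.32. Across genes with at least 50 counts, the fold changes of gun1 and fug1 correlated at 0.896. Without each library in turn, the correlations were 0.749 to 0.881 (gun1 and fug1), 0.633 to 0.787 (gun1 and gun1 fug1) and 0.704 to 0.830 (fug1 and gun1 fug1). With psbA left out of all counts, plastid shares minus wild type were 1.48 (gun1), 9.52 (fug1) and -19.4 points (gun1 fug1). With psbA taken from the plastid counts but kept in the total they were -3.82, -4.24 and -17.2. For the most abundant mitochondrial gene they were 0.0845 (gun1) and 0.0296 (fug1), and 0.0842 and 0.0295.

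Log2 fold changes of genes, and medians of lists, reversed as follows. By library totals, in fug1: light-harvesting proteins -0.83, LHCB4.3 -0.38, CSD2 -0.23, CYP79B2 -0.29, CYP83B1 -0.54 and GI -0.035. In gun1 fug1: plastid-encoded ribosomal proteins -0.22, psbC -0.32 and TOC1 -0.15. In D/gun1: plastid translation factors -0.074, plastid transcription machinery -0.019, plastid chaperones -0.11 and GUN1 -0.45. With the root score as a covariate, in gun1: plastid-encoded NDH genes 0.31, plastid-encoded ribosomal proteins 0.76, nuclear-polymerase genes 1.07, root markers -0.096, FUG1 0.16, accD 0.12 and rpoC1 0.68. In fug1: tetrapyrrole 0.060, plastid-encoded NDH genes 1.41, FNR2 0.038, GNC 0.14, SIGA 0.20, CPN60B 0.032, ndhJ 0.41, RVE8 0.21 and LRX1 -0.15. In gun1 fug1: plastid proteases 0.044, CHLI2 0.067, PTM 0.11, GNC 0.80, PTAC7 0.38, SIGE 1.00, RVE8 0.29 and PRP1 -0.21. With the root score and without gun1 fug1 3, in gun1: nuclear photosystem genes 0.057, plastid-encoded ribosomal proteins 0.15, nuclear-polymerase genes 0.048, root markers -0.18, FUG1 0.21, SCO1 0.019 and SIGE 0.095. In fug1: tetrapyrrole 0.25, nuclear-encoded plastid ribosomal proteins 0.11, plastid translation factors 0.35, plastid-encoded NDH genes 0.62, GUN1 0.065, PHT1;1 -0.095, LHCB3 0.24, FNR2 0.092, HCEF1 0.15, HEMA1 0.094, GNC 0.50, RRF 0.14, PTAC7 0.068, SIGA 0.27, ndhJ 0.33, RVE8 0.30, LHY 0.17 and LRX1 -0.068. In gun1 fug1: nuclear photosystem genes 0.19, nuclear-encoded plastid ribosomal proteins 0.077, plastid proteases 0.23, root markers -0.16, CHLI1 0.060, CHLI2 0.32, PTM 0.12, GNC 1.44, PTAC7 0.87, SIGE 1.53, psaA 0.020, RVE8 0.45 and TOC1 -0.30. In D/fug1: nuclear-encoded plastid ribosomal proteins 0.035. In D/gun1: nuclear photosystem genes 0.10 and nuclear-encoded plastid ribosomal proteins 0.20. With the block and without gun1 fug1 3, in D/fug1: FUG1 -0.15.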

Other observations

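All comparisons in this part leave out gun1 fug1 3, and the genes were chosen after their values were seen.

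HSP21 (AT4G27670), a small heat shock protein gene of the plastid, was too low to be tested with all 12 libraries. It had 0, 0 and 0 counts in fug1, 0, 1 and 1 in wild type and 7, 3 and 2 in gun1 (0.153 to 0.482 CPM). In gun1 fug1 1, 2 and 3 it had 126, 83 and 2 counts (9.56, 7.71 and 2.40 CPM), where 3 counts, or 3.60 CPM in gun1 fug1 3, mark the floor. In gun1 fug1, the cytosolic HSP18.2 (AT5G59720) rose against wild type (5.11 ± 0.53, adjusted p = 7.32e-07) and fug1 (5.99 ± 0.70, adjusted p = 6.39e-05). The 6 heat shock genes tested had a median of 3.50 against wild type (camera adjusted p = 1.73e-05, estimated-correlation p = 0.264). The filter may select for this rise.

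Of 33 plastid-encoded photosynthesis genes, 16 were lower and 3 higher in gun1 fug1 against wild type, and 14 lower and 0 higher against fug1 (median -1.17, camera adjusted p = 6.07e-23, estimated-correlation p = 0.282). In the interaction 16 genes lay below the sum of the single mutant effects, and the median was -1.28, against 0.60 with all 12 libraries (camera adjusted p = 3.04e-09, estimated-correlation p = 0.476).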
